A study of Mus musculus with 12 samples.

How the data were processed

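Total RNA of 12 mouse samples was sequenced, 6 labelled retina cells and 6 labelled brain microvascular pericytes, in 4 groups of 3 libraries. Per the labels, RNA was extracted with Trizol and libraries were made with the NEBNext Ultra RNA kit. The labels do not state whether libraries kept the strand, so reads of overlapping genes on opposite strands are uncertain. Per the labels, the authors checked reads with FastQC 0.11.8, aligned them with HISAT2 2.0.5, counted them with featureCounts 1.5.0-p3 and tested them with limma, with no version stated. The genome build is not given in the sources used here, and no positions are reported. The series text also describes knockdowns in a C3H10T1/2 line that match none of the 12 samples and were not used here.

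The deposited tables hold raw counts per gene, 1 table for the retina and 1 for the pericyte-labelled libraries. Tests on the tables found whole numbers, with 32285 genes in the first and 55401 in the second, of which 9649 and 26257 were 0 in all libraries. The retina table lists protein-coding, long noncoding, immunoglobulin and T cell receptor genes, and the other table lists all gene classes, so their totals are not on 1 scale and levels were not compared across tables. Mitochondrially encoded mRNAs were 0 in all retina libraries. In the pericyte-labelled libraries they took between 1.87% and 2.24% of counts. Total counts ran from 15580024 to 16842926 in the retina and from 33001248 to 37954077 in the other libraries. Pericyte columns were matched to samples by the sample descriptions in the labels, while retina columns carried 2 short names that were mapped to groups by inference, and library numbers are column numbers. Replicates differed by more than sampling noise, with the lowest chi-squared per degree of freedom within a group at 11.3 in the retina and 6.13 in the other libraries, so no 2 columns were copies. No column was left out.

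Each table was fitted on its own in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr with a minimum count of 10, library sizes were scaled by TMM, and the robust quasi-likelihood F test compared vesicles with PBS, with 4 residual degrees of freedom. Benjamini-Hochberg adjusted p under 0.05 in a 2-sided test made a call. The standard error was the size of the log2 fold change divided by the square root of F. CPM values used TMM-scaled library sizes. The biological coefficient of variation was 0.203 in the retina and 0.0818 in the other libraries. An exact permutation test of 3 against 3 libraries cannot give a 2-sided p under 0.1, so gene p-values come from the model across genes. Where a group had 0 counts, the fold bound used 3 counts over the group, and ratios from 1 to 3 counts carry a 95% exact counting interval. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

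Before the data were examined, 42 gene lists and a name pattern for ribosomal proteins were fixed from general knowledge, covering cell types that the samples could hold and immune, injury, stress and metabolic programmes. The pattern also takes in S6 kinases, which are not ribosomal proteins. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation, which also refers its statistic to the few residual degrees of freedom, was run beside it. So were fry directional, which asks whether genes of a list move on balance 1 way, and fry mixed, which asks whether they change in either direction. Genes named in the text were chosen by a rule fixed then. It took the 10 called genes with the largest change in each direction that had no overlap between groups and a mean of at least 1 CPM in the higher group, leaving out unnamed gene models. It added up to 4 genes of each described list in order of p. Not every gene that this took in is reported here. It also added Ccl2, Ly6c2, Cx3cr1, Gfap and Rbpms in the retina and Ccl2, Pdgfrb, Rgs5 and Acta2 in the other libraries. Genes named to identify a small count of list members, genes given as shared by both comparisons, and markers whose choice is stated beside them fall outside that rule and were chosen after their values were seen.

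Overlap of called genes was tested with Fisher's exact test over the 13712 genes tested in both tables. The difference between the vesicle effects was fitted jointly with limma (voom with a weight per table) and camera, a test chosen after the data were examined. An earlier form of it, by relabelling libraries, could not reach significance on simulated data and was replaced before use on the real counts.

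The test was tried on simulated counts made from each table. Each gene took its spread from the trend over genes, and changes were planted only in genes with at least 20 expected counts. Real genes can vary more between libraries, so recovery and false calls on the real counts could be worse. In the retina it recovered 19.7% of 66 genes changed 1.5-fold, 70.1% of 67 changed 2-fold and 97.0% of 67 changed 4-fold, with 5 false among 146 calls. In the other libraries it recovered 65.2%, 91.0% and 97.0%, with 7 false among 192 calls. Of 20 random lists camera called 0 in each. Genes were simulated independently of each other, so neither these lists nor those of the difference test show how camera acts on correlated genes. On 13314 simulated genes the difference test gave a list raised in 1 table adjusted p = 8.7e-70 and a list raised in both 0.946, called 0 of 20 random lists, and recovered 10 of 20 genes with 0 false calls.

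Alternatives fixed before the data were examined were leaving out each library, DESeq2 1.42.0, relative log expression size factors, no TMM scaling, no low-count filter, a filter at 10 CPM in 3 libraries, an added fold threshold, adjusted p under 0.1, unadjusted p under 0.01 for the overlap, and the replicate number as a block. Added after seeing the data were the summed lens level as a covariate, leaving out the library with the most lens counts in each group, leaving out lens genes before scaling, and the ribosomal list without S6 kinases. The summed level of contractile genes was a covariate in a further fit, added after seeing the data and used only to weigh carried-over tissue. Pseudocount alternatives apply only to normalised values and were not used here.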

Results

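The data were bulk RNA counts per gene from 12 mouse libraries in 4 groups of 3. Of these, 6 came from samples labelled retina cells, taken 1 day after optic nerve crush, the injury that the labels shorten to ONC. Their groups were crush with phosphate-buffered saline (PBS) and crush with small extracellular vesicles of mesenchymal stem cells (MSC.sEV in the labels), the vesicles marked i.o., which the labels do not spell out. The label of the PBS group has no such mark. The other 6 came from samples labelled brain microvascular pericytes, given PBS or the vesicles for 12 hours. Retina libraries held 15580024, 16014289 and 16264189 counts with PBS and 15857874, 16842926 and 15665800 with vesicles. Pericyte-labelled libraries held 37954077, 33001248 and 36577138 with PBS and 34580643, 36964612 and 37492365 with vesicles. Levels are in CPM, counts scaled to a common library total. A count of 3 in 1 library came to between 0.180 and 0.196 CPM in the retina and between 0.0778 and 0.0895 CPM in the pericyte-labelled libraries. The series title concerns monocytes and macrophages with low Ly6C in the retina and protection of the optic nerve. The retina comparison asked which mRNAs the vesicles changed after the injury, and the other asked which they changed in cells labelled pericytes. Retina columns were read as crush with PBS and crush with vesicles by inference from their short names, so the direction of every retina change rests on that reading. If the control columns were uninjured retina, each retina difference would hold the effect of the crush together with that of the vesicles. The labels do not say whether the 3 libraries of a group came from separate animals or cultures. No genome build is given in the sources used here, so genes carry symbols and no positions. Values below are mean CPM ± SD over 3 libraries per group, and log2 fold changes are vesicles minus PBS ± SE. Medians given for lists are of log2 fold change, and a pair of counts adjusted over the list alone gives genes higher, then lower. Fold bounds and ratios from few counts use 3 counts over a group as the floor and cover counting error only.

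In the injured retina, mRNAs of inflammatory cytokines and NF-kB targets, chemokines and markers of neutrophils, monocytes and macrophages were higher with vesicles than with PBS. With an estimated correlation these 4 list calls were lost (adjusted p from 0.13 to 0.14). Lcn2 (ENSMUSG00000026822), an iron-sequestering acute-phase protein, rose from 64.2 ± 9.59 to 2039.5 ± 428 CPM (log2 fold change 4.99 ± 0.20, adjusted p = 2.1e-05). Cxcl1, a chemokine that attracts neutrophils, rose from 0.394 ± 0.0799 to 113 ± 49.5 CPM (log2 fold change 8.15 ± 0.48, adjusted p = 0.00029). Csf3, the growth factor of the neutrophil lineage, had 1 count over the PBS libraries and 1230 over the vesicle libraries, a ratio of 1248 (95% counting interval 224 to 49336) with adjusted p = 0.00095. Lower mRNAs included those of photoreceptors, list calls that were also lost with an estimated correlation (0.40 for rods and 0.15 for cones). Homeostatic microglia markers moved both ways (4 of 13 higher, 4 lower), and Siglech among them went from 3.28 ± 0.296 to 0.335 ± 0.0307 CPM (log2 fold change -3.26 ± 0.35, adjusted p = 0.00044).

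Of 15440 genes tested in the retina with edgeR, 2449 were called at adjusted p under 0.05, 1648 higher and 801 lower with vesicles. At least 2-fold changes numbered 1070 higher and 125 lower among them. Of the called genes, 2446 had no overlap between the groups, and of all tested genes 35.7% had none, against 10% by chance. Without PBS library 2 the test called 1328 genes (1051 higher, 277 lower), without vesicle library 1 it called 1401 (1048 and 353), and without vesicle library 2 it called 1381 (1085 and 296). Lens mRNAs made up 0.706%, 0.0746% and 0.0651% of counts in the PBS libraries and 1.89%, 7.19% and 0.0120% in the vesicle libraries. Without the library richest in lens mRNAs in each group, an alternative added after seeing the data, 1420 genes were called (1058 higher, 362 lower).

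Among the 10 genes with the largest rise in the retina, Orm1, an acute-phase plasma protein, was listed at 0 in all PBS libraries and at 24.0 ± 9.38 CPM with vesicles, at least 387-fold higher (adjusted p = 0.00052). Il19, a cytokine of the interleukin-10 family, was at 0 and 17.0 ± 11.4 CPM, at least 275-fold higher (adjusted p = 0.012, and 0.076 with no low-count filter). Saa3, a serum amyloid protein, rose from 0.399 ± 0.237 to 104 ± 59.2 CPM (log2 fold change 8.01 ± 0.77, adjusted p = 0.0040), and Orm2 from 0.109 ± 0.188 to 23.9 ± 10.6 CPM (log2 fold change 7.75 ± 0.77, adjusted p = 0.0017). Tnfrsf26, Soat2, Cd69 and Serpina3m were at 0 in all PBS libraries and at least 43.7-fold, 28.5-fold, 27.9-fold and 25.1-fold higher. Soat2 esterifies cholesterol, Cd69 marks recently activated leukocytes and Serpina3m inhibits proteases. The Orm and Serpina3 families have near-identical copies, so how reads were shared between them is uncertain.

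Among the 10 genes with the largest fall in the retina, Siglech, a surface lectin of microglia, led. Calr4 (log2 fold change -2.81 ± 0.49, adjusted p = 0.0047), Esrp1 (log2 fold change -2.66 ± 0.30, adjusted p = 0.00055), a splicing regulator, and Sh3tc2 (log2 fold change -2.54 ± 0.51, adjusted p = 0.0087) fell and stayed called without any 1 library, though Calr4 and Sh3tc2 lost the call in the fit without the lens-rich libraries (adjusted p = 0.0505 and 0.0702). The other 6 lost the call in some fits without 1 library, with log2 fold changes between -2.07 and -1.36 in those fits. Elf5 (log2 fold change -2.06 ± 0.56, adjusted p = 0.034) lost the call without PBS library 2 or 3 or vesicle library 1 or 2 (adjusted p from 0.103 to 0.123). Lhx1os (log2 fold change -2.02 ± 0.41, adjusted p = 0.0094), an antisense RNA whose reads could not be told from the other strand, lost it without vesicle library 1 (0.052). Hes5, a Notch target gene (log2 fold change -1.87 ± 0.40, adjusted p = 0.012), lost it without PBS library 2 (0.068) or vesicle library 2 (0.0505). Gpr34, a receptor of microglia (log2 fold change -1.79 ± 0.41, adjusted p = 0.018), lost it without PBS library 1 (0.055), PBS library 3 (0.0503) or vesicle library 1 (0.0509). Slc22a29 (log2 fold change -1.79 ± 0.39, adjusted p = 0.014) lost it without PBS library 2 or vesicle library 1 or 2 (from 0.0606 to 0.0661). Slc30a10, a manganese exporter (log2 fold change -1.78 ± 0.51, adjusted p = 0.041), lost it without any library but vesicle library 3 (from 0.079 to 0.124).

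Recruitment signals rose together in the retina. Of 27 tested chemokine genes, 20 rose and 0 fell (21 and 0 adjusted over the list alone, median 3.05, camera adjusted p = 2.8e-25, adjusted p = 0.13 with an estimated correlation). Ccl17 went from 0.376 ± 0.141 to 12.1 ± 4.27 CPM and Ccl3 from 0.605 ± 0.424 to 28.3 ± 4.77 CPM. Ccl2, which attracts monocytes that carry its receptor, rose from 2.40 ± 0.982 to 107 ± 41.2 CPM (log2 fold change 5.48 ± 0.43, adjusted p = 0.0011). In the list of inflammatory cytokines and NF-kB targets, 25 of 26 genes rose and Tnfaip3, an inhibitor of the pathway, fell (log2 fold change -0.90 ± 0.10, adjusted p = 0.00045) (25 and 1 adjusted over the list alone, median 4.03, camera adjusted p = 1.6e-58, adjusted p = 0.13 with an estimated correlation). Il1a rose from 1.46 ± 0.592 to 36.5 ± 2.65 CPM, Ptgs2 from 1.22 ± 0.207 to 25.4 ± 7.45 CPM and Nfkbia from 26.0 ± 1.58 to 106 ± 18.8 CPM. Among 11 leukocyte adhesion molecules, 5 rose (Icam1, Vcam1, Madcam1, Cd44 and Vcan) and Jam2 fell (5 and 1 adjusted over the list alone, median 0.43, camera adjusted p = 6.9e-05, adjusted p = 0.15 with an estimated correlation). Icam1 rose from 0.537 ± 0.0650 to 13.4 ± 4.47 CPM and Vcam1 from 26.3 ± 3.88 to 112 ± 27.8 CPM.

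Interferon-stimulated and antigen-presenting genes were also higher in the retina with vesicles. Of 39 interferon-stimulated genes, 31 rose and 0 fell (34 and 1 adjusted over the list alone, median 1.86, camera adjusted p = 1.1e-22, adjusted p = 0.23 with an estimated correlation). Gbp6, a guanylate-binding protein, rose from 5.70 ± 0.991 to 26.0 ± 4.32 CPM, Stat2 from 17.3 ± 0.899 to 49.2 ± 8.48 CPM and Irf1 from 7.72 ± 0.724 to 25.5 ± 4.42 CPM. Of 16 antigen presentation genes, 14 rose and 0 fell (16 and 0 adjusted over the list alone, median 1.96, camera adjusted p = 3.3e-19, adjusted p = 0.15 with an estimated correlation). H2-Aa, a class II chain, rose from 3.93 ± 1.05 to 52.7 ± 9.28 CPM (log2 fold change 3.74 ± 0.22, adjusted p = 5.1e-05) and H2-Eb1 from 2.72 ± 0.584 to 18.3 ± 2.88 CPM. The H2 and Gbp families hold close copies that could share reads. Among 23 complement and coagulation genes, 13 rose and 0 fell (18 and 0 adjusted over the list alone, median 1.8, camera adjusted p = 3.5e-17, adjusted p = 0.15 with an estimated correlation). C3 went from 4.94 ± 0.629 to 119 ± 36.9 CPM and F13a1 from 1.19 ± 0.147 to 11.1 ± 1.42 CPM.

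Markers of myeloid cells rose in the same retina libraries. Of 25 monocyte and macrophage markers, 24 rose and 0 fell (25 and 0 adjusted over the list alone, median 2.87, camera adjusted p = 6.2e-49, adjusted p = 0.14 with an estimated correlation). Lyz2 rose from 35.5 ± 4.59 to 603 ± 128 CPM (log2 fold change 4.08 ± 0.19, adjusted p = 2.3e-05), and Ptprc, the pan-leukocyte antigen CD45, from 2.56 ± 0.601 to 32.3 ± 6.74 CPM (log2 fold change 3.66 ± 0.23, adjusted p = 4.0e-05). Of 12 neutrophil markers, 11 rose and 0 fell (11 and 0 adjusted over the list alone, median 4.86, camera adjusted p = 1.8e-28, adjusted p = 0.14 with an estimated correlation). G0s2 rose from 3.83 ± 1.01 to 40.6 ± 12.2 CPM, and Stfa2l1 had 2 counts over the PBS libraries against 273, a ratio of 139 (95% counting interval 38.0 to 1149). In the list of Ly6C-low monocyte markers, 5 of 11 rose (Itgal, Cebpb, Klf2, Treml4 and Ace) and Cd36 fell (5 and 1 adjusted over the list alone, median 0.72, camera adjusted p = 0.00012, adjusted p = 0.18 with an estimated correlation). Itgal rose from 0.537 ± 0.0130 to 10.9 ± 0.911 CPM and Cebpb from 3.15 ± 0.193 to 34.9 ± 8.53 CPM. Klf2 and Treml4 lost the call without PBS library 2 or vesicle library 1 (adjusted p from 0.0582 to 0.0789), and Ace and Cd36 lost it without any library but vesicle library 3 (from 0.0504 to 0.174). Among 15 markers of alternative activation and repair macrophages, 7 rose and 0 fell (10 and 1 adjusted over the list alone, median 1.54, camera adjusted p = 7.3e-06, adjusted p = 0.15 with an estimated correlation). Spp1 went from 76.4 ± 6.44 to 191 ± 33.1 CPM and Mrc1 from 1.31 ± 0.289 to 6.98 ± 2.48 CPM.

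Ly6c2, a gene of the Ly6C surface antigen by which monocytes are parted into high and low classes, went from 2.33 ± 1.70 to 15.5 ± 7.02 CPM (log2 fold change 2.74 ± 0.68, adjusted p = 0.048). Whether it shared reads with close copies was not tested. The call of Ly6c2 was lost without PBS library 1 (adjusted p = 0.061) or 3 (0.117) and without vesicle library 1 (0.117), 2 (0.125) or 3 (0.067), and over all alternatives its adjusted p ran from 0.0074 to 0.138. Cx3cr1, the fractalkine receptor of microglia and Ly6C-low monocytes, was at 2.96 ± 0.460 CPM with PBS and 3.75 ± 0.641 CPM with vesicles (log2 fold change 0.34 ± 0.27, adjusted p = 0.44). Homeostatic microglia markers moved both ways. Of 13, 4 rose (Selplg, Csf1r, Fcrls and P2ry13) and 4 fell, among them Siglech, P2ry12 and Gpr34 (4 and 4 adjusted over the list alone, median 0.94, camera adjusted p = 0.93, adjusted p = 0.97 with an estimated correlation). For this list the test pointed down while the median and the mean log2 fold change (0.33) lay above 0. P2ry12, a purinergic receptor of resting microglia, fell from 10.2 ± 1.29 to 3.87 ± 0.642 CPM (log2 fold change -1.40 ± 0.22, adjusted p = 0.0028). Fcrls lost the call without PBS library 2 (0.0699) or vesicle library 1 (0.0625), and P2ry13 lost it without any library but vesicle library 3 (from 0.0815 to 0.194).

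Reactive gliosis genes were higher after vesicles, and 16 of the 30 genes of that list stand in other lists too, among them Lcn2 and C3. In the list, 25 of 29 rose and 0 fell (26 and 0 adjusted over the list alone, median 2.97, camera adjusted p = 1.5e-55, adjusted p = 0.14 with an estimated correlation). Ednrb, an endothelin receptor, rose from 6.95 ± 0.838 to 33.8 ± 5.69 CPM and the metallothionein Mt1 from 241 ± 70.6 to 1893 ± 204 CPM. Gfap, the intermediate filament of reactive glia, rose from 43.8 ± 12.4 to 146 ± 46.8 CPM (log2 fold change 1.73 ± 0.30, adjusted p = 0.014), a call lost without PBS library 1 (adjusted p = 0.075), with adjusted p from 8.5e-13 to 0.079 over the alternatives. Müller glia markers were mixed, with 3 of 21 higher (Dbi, Sox9 and Crym) and 2 lower (Gpr37 and Aqp4) (5 and 6 adjusted over the list alone, median 0.03, camera adjusted p = 0.22, adjusted p = 0.66 with an estimated correlation). Gpr37 fell from 116 ± 19.2 to 40.3 ± 10.2 CPM and Dbi rose from 195 ± 19.5 to 405 ± 103 CPM. Aqp4 lost the call without PBS library 1 or 2 or vesicle library 1 or 2 (adjusted p from 0.0680 to 0.0928). Sox9 lost it without PBS library 1 or 2 or vesicle library 2 or 3 (from 0.0578 to 0.113), and Crym without any library but PBS library 1 (from 0.0979 to 0.148).

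**Figure D1:**
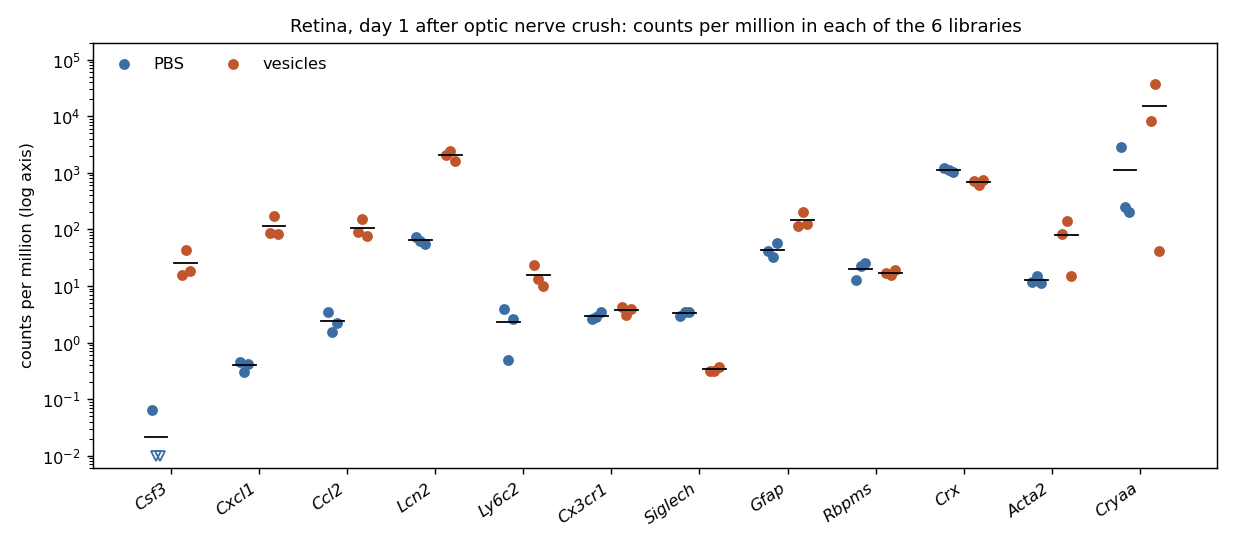
CPM (log axis) of 12 genes in each of the 6 retina libraries, PBS beside vesicles, with a black bar at each group mean and an open triangle for a library at 0. Lcn2 lay between 55.5 and 74.5 CPM with PBS and between 1614 and 2471 CPM with vesicles, while Cryaa, a lens crystallin, differed more between libraries of 1 group than between the groups.

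Photoreceptor and bipolar cell genes were lower in vesicle-treated retina. Of 24 rod genes, 0 rose and 17 fell (0 and 20 adjusted over the list alone, median -0.48, camera adjusted p = 4.3e-07, adjusted p = 0.40 with an estimated correlation). Crx, a transcription factor of photoreceptors, fell from 1119 ± 91.6 to 693 ± 63.3 CPM (log2 fold change -0.69 ± 0.11, adjusted p = 0.0029), and Nr2e3, a rod transcription factor, from 456 ± 25.3 to 241 ± 53.4 CPM. Of 15 cone genes, 6 fell and Gnb3 rose (1 and 8 adjusted over the list alone, median -0.40, camera adjusted p = 0.0010, adjusted p = 0.15 with an estimated correlation). Cone arrestin, Arr3, fell from 322 ± 31.6 to 196 ± 9.26 CPM, and Gnb3 lost its call without PBS library 2 (adjusted p = 0.058) or vesicle library 1 (0.056). Among 17 bipolar cell markers, 0 rose and 10 fell (0 and 10 adjusted over the list alone, median -0.53, camera adjusted p = 3.0e-05, adjusted p = 0.28 with an estimated correlation). Prkca went from 118 ± 10.9 to 73.0 ± 8.11 CPM and Grm6 from 21.7 ± 3.44 to 12.1 ± 2.08 CPM, the second not called without PBS library 2 (0.054). In the list of amacrine and horizontal cell markers 2 of 20 fell (0 and 2 adjusted over the list alone, median -0.40, camera adjusted p = 0.0031, adjusted p = 0.50 with an estimated correlation), namely Tfap2b and Sept4, which lost the call without PBS library 2 or vesicle library 1 or 2, and Sept4 also without PBS library 1 (adjusted p from 0.0570 to 0.0802). The list test with fry, directional, did not call that list (adjusted p = 0.155).

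Retinal ganglion cells are the neurons whose axons the crush injures. Of 20 markers of these cells, 0 rose and 3 fell (0 and 3 adjusted over the list alone, median -0.31, camera adjusted p = 0.0053, adjusted p = 0.64 with an estimated correlation), with adjusted p = 0.260 in fry, directional. Jam2 fell from 135 ± 4.96 to 92.2 ± 9.76 CPM (log2 fold change -0.55 ± 0.10, adjusted p = 0.0057). Chrna6 (log2 fold change -0.62 ± 0.15, adjusted p = 0.019) and Sncg (log2 fold change -0.59 ± 0.16, adjusted p = 0.036) each lost the call without any library but vesicle library 3 (adjusted p from 0.050 to 0.083 and from 0.063 to 0.13). All 20 had log2 fold changes below 0. So had all 20 amacrine and horizontal cell markers, all 24 rod genes, 16 of 17 bipolar cell markers and 13 of 15 cone genes. The shared sign was therefore not particular to ganglion cells. Thy1, a surface protein of ganglion cells, was at 244 ± 51.7 CPM with PBS and 169 ± 33.6 CPM with vesicles (log2 fold change -0.53 ± 0.19, adjusted p = 0.11), and was called with DESeq2 (0.017), without PBS library 1 (0.031) and without vesicle library 3 (0.027). Rbpms, which marks ganglion cells, was at 20.2 ± 6.56 CPM with PBS and 17.3 ± 1.46 CPM with vesicles (log2 fold change -0.22 ± 0.23, adjusted p = 0.56). In the axon injury response, 7 of 23 genes rose and 2 fell, Trib3 and Csrp3 (8 and 3 adjusted over the list alone, median 0.42, camera adjusted p = 0.0052, adjusted p = 0.23 with an estimated correlation). Atf3, a transcription factor of injured neurons and stressed cells, rose from 8.79 ± 1.21 to 51.3 ± 9.84 CPM (log2 fold change 2.54 ± 0.18, adjusted p = 5.9e-05) and Gap43, a growth cone protein, from 57.6 ± 2.99 to 92.0 ± 5.69 CPM. Trib3 lost the call in each fit that left out 1 library (from 0.0532 to 0.182), and Csrp3 in each but that without vesicle library 3 (from 0.0598 to 0.154). Of the 25 genes of the axon injury list, 13 stand in other lists too, Trib3 among them.

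Stress, matrix and growth factor programmes also moved in the retina. Of 29 immediate early genes 14 rose and 0 fell (16 and 0 adjusted over the list alone, median 0.86, camera adjusted p = 5.0e-09, adjusted p = 0.28 with an estimated correlation). Junb went from 21.5 ± 3.52 to 131 ± 33.2 CPM. The antioxidant response had 11 of 22 genes higher and 0 lower (12 and 1 adjusted over the list alone, median 0.65, camera adjusted p = 2.4e-08, adjusted p = 0.23 with an estimated correlation). Hmox1 went from 10.1 ± 0.902 to 43.9 ± 9.84 CPM. Among 18 p53 targets, 7 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.30, camera adjusted p = 0.0010, adjusted p = 0.15 with an estimated correlation). Fas went from 1.54 ± 0.529 to 40.8 ± 9.89 CPM. Extracellular matrix and remodelling genes had 11 of 36 higher and 0 lower (17 and 0 adjusted over the list alone, median 1.32, camera adjusted p = 1.3e-08, adjusted p = 0.28 with an estimated correlation), and Timp1, an inhibitor of matrix proteases, rose from 5.26 ± 0.863 to 551 ± 205 CPM (log2 fold change 6.71 ± 0.38, adjusted p = 0.00029). Neurotrophic and growth factors had 5 of 19 higher (Lif, Bdnf, Clcf1, Fgf2 and Grn) and Ptn lower (9 and 2 adjusted over the list alone, median 0.79, camera adjusted p = 0.018, adjusted p = 0.49 with an estimated correlation). That list call was lost without PBS library 3 (adjusted p = 0.0589). Lif, a cytokine of the interleukin-6 family, went from 0.377 ± 0.185 to 7.58 ± 1.78 CPM and Bdnf from 12.8 ± 2.09 to 22.5 ± 2.41 CPM. Clcf1 lost the call without PBS library 2 or vesicle library 1 or 2 (from 0.0548 to 0.0617). Fgf2 lost it without PBS library 3 or any vesicle library (from 0.0573 to 0.0929), and Grn without PBS library 1 or 2 or vesicle library 1 or 2 (from 0.127 to 0.152).

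Contractile genes and tissue next to the retina varied between libraries. Of 16 smooth muscle and contractile genes, 4 rose (Flna, Cald1, Actn1 and Cnn2) and 0 fell (5 and 0 adjusted over the list alone, median 0.82, camera adjusted p = 0.0031, adjusted p = 0.50 with an estimated correlation), with adjusted p = 0.092 in fry, directional. Cald1 lost the call without PBS library 1 or 2 (0.0645 and 0.0617), Actn1 without PBS library 2 or vesicle library 2 (0.0595 and 0.0587), and Cnn2 without PBS library 1 or 2 or vesicle library 1 (from 0.0541 to 0.0826). The summed level of contractile genes was 182, 201 and 230 CPM in the PBS libraries and 438, 581 and 260 CPM with vesicles. Acta2, smooth muscle actin, chosen after its values were seen, was at 11.7, 14.9 and 11.5 CPM with PBS and 83.8, 141 and 14.8 CPM with vesicles (log2 fold change 2.65 ± 0.89, adjusted p = 0.14, and 0.00021 without vesicle library 3). None of 23 lens genes was called by edgeR, none had unadjusted p under 0.05, and DESeq2 called 3 higher (0 and 0 adjusted over the list alone, median 2.86, camera adjusted p = 0.55, adjusted p = 0.96 with an estimated correlation). Of 18 genes of retinal pigment epithelium and melanocytes, edgeR called 0, 2 had unadjusted p under 0.05 and DESeq2 called 1 (0 and 0 adjusted over the list alone, median 1.17, camera adjusted p = 0.035, adjusted p = 0.64 with an estimated correlation). That list lost its call without PBS library 1 (adjusted p = 0.111) or vesicle library 2 (0.103), with the lens covariate (0.114) and without the lens-rich libraries (0.294).

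Over the 41 lists with at least 5 tested genes in the retina, camera with a preset correlation called 28, 22 higher and 6 lower, and with an estimated correlation it called 0, with 12 at unadjusted p under 0.05. In the fit without the library richest in lens mRNAs in each group, 42 of the genes followed through the alternatives kept their direction but lost the call (adjusted p from 0.0505 to 0.281), among them Cd44, Jam2, Gpr37, Ptn, Bdnf and Csf1r.

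In the libraries labelled pericytes, chemokine, NF-kB and interferon-stimulated mRNAs were higher after 12 hours with vesicles. Nos2, the inducible nitric oxide synthase, rose from 0.178 ± 0.11 to 51.8 ± 2.90 CPM (log2 fold change 8.19 ± 0.18, adjusted p = 1.6e-18). Cxcl10, an interferon-induced chemokine, rose from 8.68 ± 1.58 to 427 ± 30.7 CPM (log2 fold change 5.62 ± 0.10, adjusted p = 3.9e-19) and Lcn2 from 1.38 ± 0.398 to 118 ± 5.61 CPM (log2 fold change 6.42 ± 0.12, adjusted p = 3.9e-19). Vcam1, an adhesion molecule for leukocytes, rose from 170.5 ± 5.37 to 1281 ± 73.5 CPM (log2 fold change 2.91 ± 0.06, adjusted p = 1.6e-18). Lower mRNAs included Gja1, a gap junction protein, from 155 ± 2.90 to 95.2 ± 10.1 CPM (log2 fold change -0.70 ± 0.07, adjusted p = 8.6e-08), and Kdr, a receptor of vascular endothelial growth factor, from 4.73 ± 0.185 to 1.49 ± 0.335 CPM (log2 fold change -1.66 ± 0.22, adjusted p = 1.1e-05).

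Of 16975 genes tested in these libraries with edgeR, 3365 were called at adjusted p under 0.05, 1855 higher and 1510 lower with vesicles. At least 2-fold changes numbered 503 higher and 126 lower. Groups did not overlap for 3300 of the called genes and for 33.8% of all tested genes. Without the TMM scaling, 3562 genes were called, 1512 higher and 2050 lower, so the share of higher genes among those called was 55.1% with it and 42.4% without it. Genes called lower numbered 993 without PBS library 3.

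The 10 genes with the largest rise in the pericyte-labelled libraries were Nos2, Lcn2 and 8 others. Csf3 had 2 counts over the PBS libraries against 640, a ratio of 326 (95% counting interval 89.9 to 2698). Ccl20, a chemokine, had 1 count against 339, a ratio of 345 (95% counting interval 61.6 to 13684). Oas3, an antiviral enzyme, had 1 count against 216, a ratio of 220.1 (95% counting interval 39.1 to 8734). Il1b rose from 0.0985 ± 0.0663 to 9.91 ± 2.82 CPM, Ccl5 from 0.214 ± 0.203 to 18.1 ± 0.795 CPM, Cxcl1 from 6.05 ± 1.55 to 462 ± 61.9 CPM, Slfn5 from 0.0713 ± 0.0827 to 5.45 ± 0.423 CPM and Cxcl3 from 0.0684 ± 0.0961 to 4.23 ± 1.20 CPM. Among the 10 genes with the largest fall, Trpc7, a cation channel (log2 fold change -2.09 ± 0.32, adjusted p = 4.9e-05), Dok7 (log2 fold change -1.97 ± 0.48, adjusted p = 0.0048), Gdap1 (log2 fold change -1.73 ± 0.41, adjusted p = 0.0040), Sncaip (log2 fold change -1.71 ± 0.20, adjusted p = 1.4e-06) and Kdr stayed called without any 1 library. Gpr12 (log2 fold change -2.39 ± 0.61, adjusted p = 0.0070) lost the call without PBS library 1 (0.0698), and Slc35f3 (log2 fold change -1.70 ± 0.47, adjusted p = 0.012) did too (0.114). Kcnk13, a potassium channel (log2 fold change -1.73 ± 0.43, adjusted p = 0.0057), lost it without PBS library 3 (0.0552). Ccdc121 (log2 fold change -1.92 ± 0.54, adjusted p = 0.014) lost it without PBS library 1 or 2 or vesicle library 1 (from 0.0507 to 0.0602). Efcab15 (log2 fold change -1.65 ± 0.49, adjusted p = 0.019) lost it without PBS library 1 or 3 or vesicle library 1 or 2 (from 0.0522 to 0.0836).

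Immune signalling lists rose in the pericyte-labelled libraries. Of 24 tested chemokine genes, 20 rose and 0 fell (22 and 0 adjusted over the list alone, median 3.02, camera adjusted p = 1.8e-69, adjusted p = 0.0092 with an estimated correlation). Ccl7 rose from 3.11 ± 0.681 to 77.6 ± 10.4 CPM and Ccl2 from 20.2 ± 5.20 to 559 ± 65.3 CPM (log2 fold change 4.79 ± 0.24, adjusted p = 0.00014). Among 28 inflammatory cytokines and NF-kB targets, 25 rose and Traf1, an adaptor of tumour necrosis factor receptors, fell (25 and 1 adjusted over the list alone, median 2.55, camera adjusted p = 1.3e-136, adjusted p = 0.0013 with an estimated correlation). Tnfaip2 rose from 25.1 ± 2.45 to 334 ± 5.27 CPM and Tlr2, a pattern-recognition receptor, from 3.64 ± 0.819 to 84.1 ± 0.960 CPM. All 41 tested interferon-stimulated genes rose (41 and 0 adjusted over the list alone, median 3.01, adjusted p = 0.0013 with an estimated correlation), and at the preset correlation the camera p was too small for the software to hold. Gbp5 went from 5.98 ± 1.18 to 200.3 ± 2.90 CPM and Ifit3 from 99.6 ± 7.35 to 1101 ± 73.1 CPM. Of 14 antigen presentation genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone, median 1.10, camera adjusted p = 1.2e-22, adjusted p = 0.020 with an estimated correlation). Tap1, a peptide transporter, went from 32.6 ± 2.72 to 139 ± 16.2 CPM. In the list of leukocyte adhesion molecules, 6 of 12 rose and 3 fell (Vcan, Jam2 and Jam3) (6 and 3 adjusted over the list alone, median 0.99, camera adjusted p = 2.5e-12, adjusted p = 0.053 with an estimated correlation), and Icam1 rose from 8.91 ± 1.01 to 74.7 ± 3.25 CPM. Jam2 lost the call without PBS library 1 or 3 or vesicle library 2 (from 0.0604 to 0.0842), and Jam3 without any library but vesicle library 1 (from 0.0944 to 0.119). Complement and coagulation had 7 of 21 genes higher and 0 lower (8 and 0 adjusted over the list alone, median 0.22, camera adjusted p = 4.4e-07, adjusted p = 0.20 with an estimated correlation). C3 went from 115 ± 4.28 to 515 ± 47.7 CPM.

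Most leukocyte markers were at low levels in these libraries. At 10 CPM or more in all 6 libraries were 2 of 26 monocyte and macrophage markers and 0 of 16 neutrophil markers. At that level were also 4 of 14 Ly6C-low monocyte, 4 of 14 homeostatic microglia and 7 of 21 alternative activation markers. Monocyte and macrophage markers had 5 of 19 higher (Cd14, Cybb, Clec4e, Ptprc and Adgre1) and 0 lower (6 and 0 adjusted over the list alone, median 0.50, camera adjusted p = 0.025, adjusted p = 0.55 with an estimated correlation), a list call lost without vesicle library 1 (adjusted p = 0.083). Cd14, a co-receptor for lipopolysaccharide, rose from 14.4 ± 2.58 to 42.9 ± 7.0 CPM and Ptprc from 0.254 ± 0.178 to 1.13 ± 0.0814 CPM. Of the 3 tested neutrophil markers, Lcn2 and Mmp9 rose and G0s2 fell, too few for a list test. Adgre1 lost the call without PBS library 1 or 3 or vesicle library 2 (from 0.0597 to 0.134), and G0s2 without PBS library 2 or 3 or vesicle library 1 or 3 (from 0.0511 to 0.261).

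Pericyte markers moved both ways. Of 16, 4 rose (Ifitm1, Cspg4, Pdgfrb and Art3) and 2 fell (Notch3 and Anpep) (6 and 2 adjusted over the list alone, median 0.17, camera adjusted p = 0.59, adjusted p = 0.78 with an estimated correlation). Pdgfrb, the platelet-derived growth factor receptor that marks pericytes, went from 59.7 ± 3.48 to 70.8 ± 4.89 CPM (log2 fold change 0.25 ± 0.07, adjusted p = 0.014). It lost the call without PBS library 2 (adjusted p = 0.0609) or 3 (0.114), without vesicle library 2 (0.0742) or 3 (0.0507), and without TMM scaling (0.0520). Art3 lost it without PBS library 2 or 3 or vesicle library 2 or 3 (from 0.0506 to 0.0978), and Anpep without PBS library 1 or 2 or vesicle library 3 (from 0.105 to 0.139). Cspg4 rose from 11.9 ± 0.900 to 17.5 ± 1.54 CPM and Notch3 fell from 25 ± 1.00 to 18.6 ± 1.57 CPM. Rgs5, another pericyte marker, was at 0.283 ± 0.199 CPM with PBS and 0.891 ± 0.430 CPM with vesicles (log2 fold change 1.66 ± 0.60, adjusted p = 0.059). It was called without vesicle library 2 (0.0499) and with no low-count filter (0.0367). Acta2 was at 572 ± 22.6 and 587 ± 15.5 CPM (log2 fold change 0.04 ± 0.06, adjusted p = 0.74), and its direction flipped without TMM scaling (-0.01, adjusted p = 0.92). Contractile genes had 3 of 18 higher (Tagln2, Actn1 and Tpm1) and 2 lower (Lmod1 and Vcl) (5 and 3 adjusted over the list alone, median 0.01, camera adjusted p = 0.99, adjusted p = 0.99 with an estimated correlation), and the median changed sign without TMM scaling. Tpm1 lost the call without TMM scaling (0.137) and without PBS library 2 or 3 or vesicle library 1 or 3 (from 0.0713 to 0.253).

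**Figure D2:**
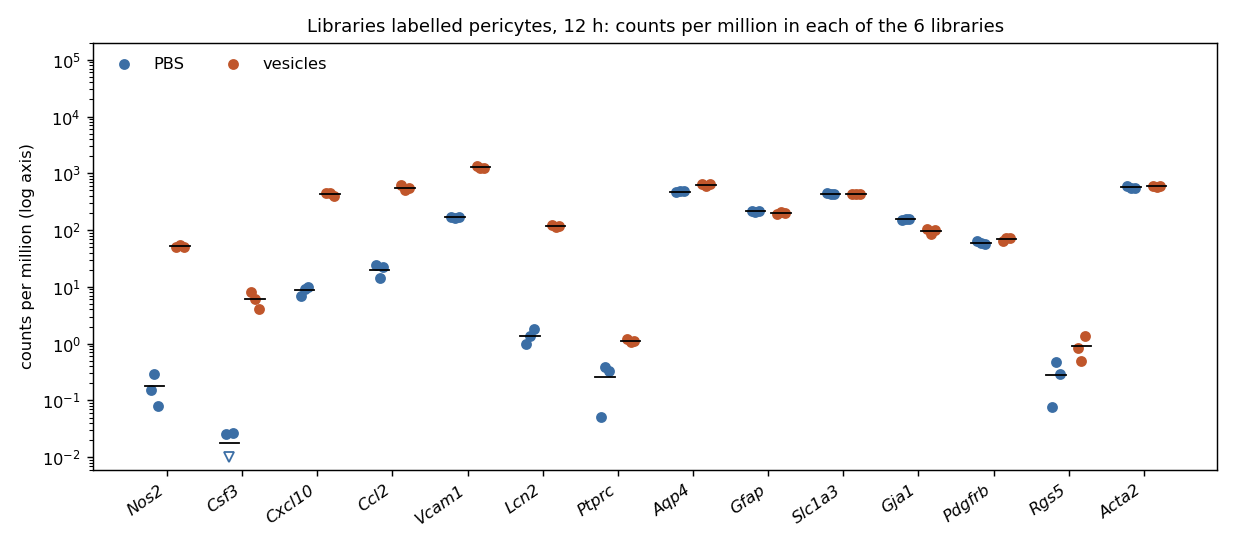
CPM (log axis) of 14 genes in each of the 6 libraries labelled pericytes, PBS beside vesicles, with a black bar at each group mean. Cxcl10 lay between 6.92 and 9.99 CPM with PBS and between 392 and 448 CPM with vesicles, and the astroglial genes Aqp4, Gfap and Slc1a3 lay above Pdgfrb in all 6 libraries.

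Glial genes formed another measured group in these libraries. Of 13 markers of astrocytes, oligodendrocytes and Schwann cells, 0 rose and 7 fell (0 and 7 adjusted over the list alone, median -0.29, camera adjusted p = 0.0054, adjusted p = 0.29 with an estimated correlation). Olig1, a transcription factor of the oligodendrocyte lineage, fell from 208 ± 2.69 to 149.7 ± 15.4 CPM and Aldoc, an enzyme abundant in astrocytes, from 271 ± 7.91 to 220.4 ± 4.22 CPM. The Müller glia list, many of whose genes astrocytes share, had 2 of 19 higher (Crym and Aqp4) and 5 lower (Kcnj10, Gpr37, Prdx6, Sox9 and Cyp26a1) (2 and 7 adjusted over the list alone, median -0.14, camera adjusted p = 0.34, adjusted p = 0.55 with an estimated correlation). Kcnj10, a potassium channel of glia, fell from 365 ± 14.7 to 247 ± 13.5 CPM, and Aqp4, a water channel, rose from 477 ± 12.4 to 623 ± 29.0 CPM. Cyp26a1 lost the call without PBS library 3 (0.0908) or vesicle library 1 (0.0634). Gfap, chosen after its values were seen, was at 215 ± 6.38 and 200.1 ± 7.18 CPM (log2 fold change -0.10 ± 0.06, adjusted p = 0.24). Among 29 reactive gliosis genes, 21 rose and 2 fell (Ednrb and Mt1) (21 and 2 adjusted over the list alone, median 0.80, camera adjusted p = 4.7e-65, adjusted p = 0.0055 with an estimated correlation). Steap4, a metalloreductase, rose from 190.4 ± 5.50 to 808 ± 23.4 CPM.

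Growth factor, injury and cell cycle lists moved as well. Neurotrophic and growth factors had 11 of 20 higher and 0 lower (13 and 0 adjusted over the list alone, median 0.82, camera adjusted p = 1.0e-06, adjusted p = 0.20 with an estimated correlation). Lif went from 4.40 ± 0.390 to 23.5 ± 3.03 CPM. Of 30 immediate early genes, 15 rose and Nr4a2 fell (15 and 1 adjusted over the list alone, median 0.50, camera adjusted p = 0.00042, adjusted p = 0.64 with an estimated correlation). Fosl2 went from 62.7 ± 6.31 to 102 ± 8.39 CPM. The p53 targets had 9 of 18 higher and 0 lower (9 and 0 adjusted over the list alone, median 0.22, camera adjusted p = 0.0032, adjusted p = 0.39 with an estimated correlation). Fas went from 118 ± 1.67 to 231 ± 15.1 CPM. In the axon injury response, 8 of 22 rose and 2 fell (Sox11 and Lcat) (9 and 2 adjusted over the list alone, median 0.30, camera adjusted p = 0.024, adjusted p = 0.55 with an estimated correlation), a list call lost without vesicle library 3 (adjusted p = 0.0603). Sox11 lost its call without PBS library 1 (0.0518) or vesicle library 2 (0.0725), and Lcat without any library but vesicle library 2 (from 0.0768 to 0.173). Cell cycle genes had Ccnd1 higher and 13 of 37 lower (1 and 23 adjusted over the list alone, median -0.17, camera adjusted p = 0.0011, adjusted p = 0.54 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell from 146 ± 5.02 to 119.8 ± 0.995 CPM.

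Over the 40 lists tested in these libraries, camera with a preset correlation called 14, 12 higher and 2 lower, and with an estimated correlation it called 5, namely chemokines, NF-kB targets, interferon-stimulated genes, antigen presentation and reactive gliosis.

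**Figure D3:**
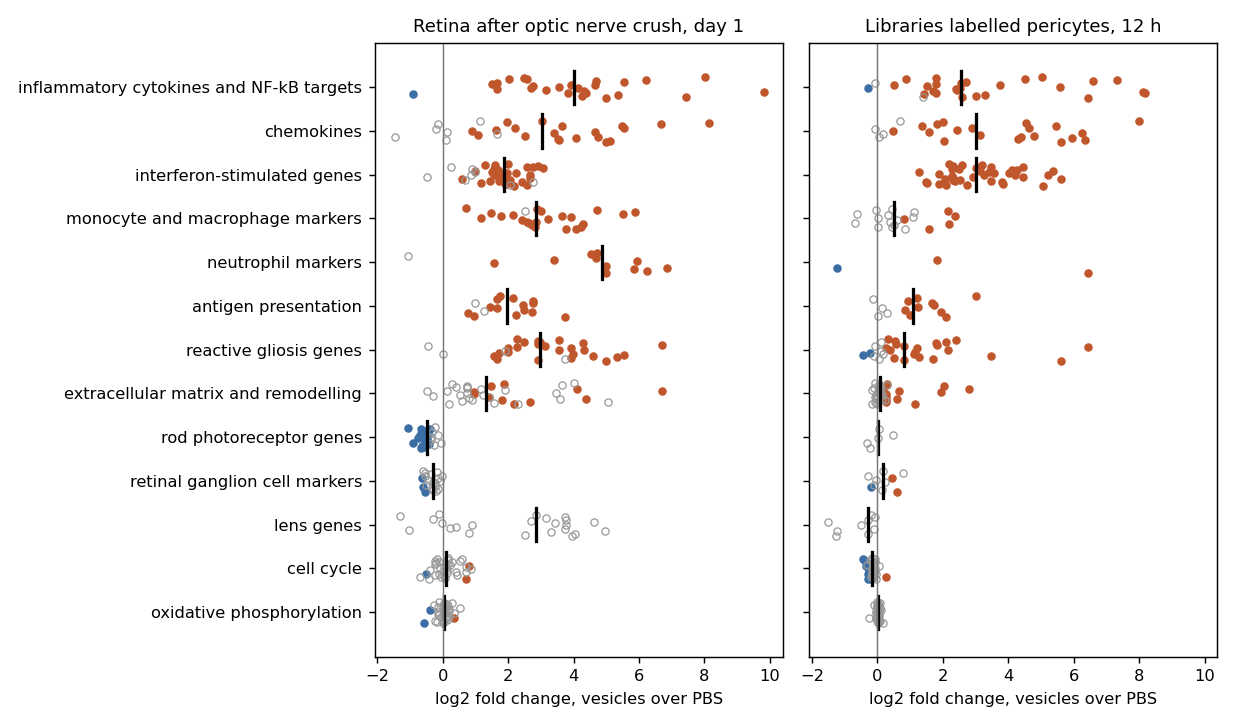
Log2 fold change, vesicles minus PBS, of each tested gene of 13 fixed lists, in the retina and in the libraries labelled pericytes. Filled red and blue points were called higher and lower, open grey points were not called, and black bars are medians of lists with at least 5 genes, such as 1.86 and 3.01 for interferon-stimulated genes.

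Many genes were changed the same way in both settings. Of 13712 genes tested in both, 1421 were higher in the retina and 1675 in the pericyte-labelled libraries, and 559 were higher in both against 174 expected (odds ratio 6.49, 95% interval 5.73 to 7.35, Fisher's exact p = 2.3e-174, two-sided). Genes lower in both numbered 101 against 61.1 expected, from 637 and 1316 (odds ratio 1.84, 1.46 to 2.30, Fisher's exact p = 3.9e-07). Fisher's exact test takes genes as independent, which they are not, so its p-values and intervals do not measure spread between libraries. Over all 13712 genes 58.5% had the same sign in both. Shared higher genes included Csf3, Cxcl1, Lcn2, Ccl2 and Icam1. Of the 783 genes called in both, 84.3% had the same sign, while 79 were higher in the retina and lower in the other libraries and 44 the reverse. Across all genes tested in both, which are not independent replicates, the log2 fold changes had Pearson's r of 0.42 and Spearman's rho of 0.26, and across the 783 genes 0.63 and 0.63. The settings differ in tissue, time and library set, so a difference between them cannot be assigned to any of these.

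**Figure D4:**
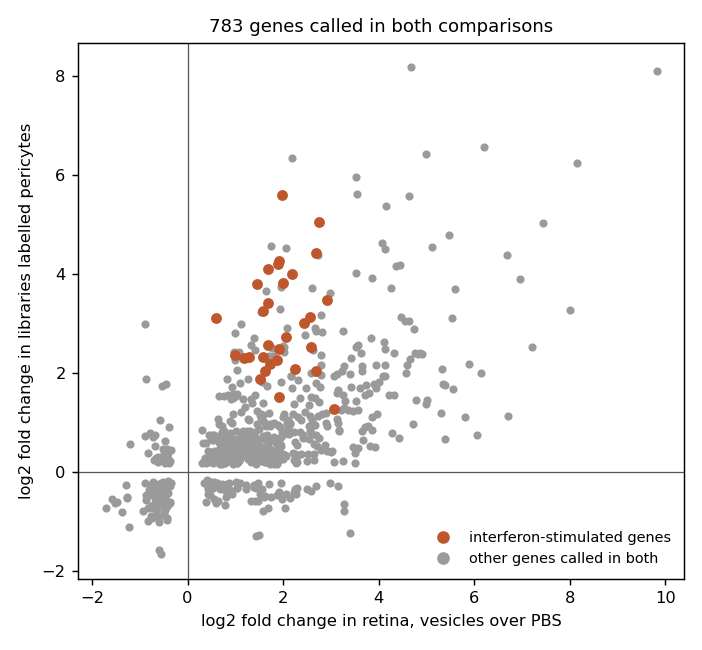
Log2 fold change in the retina (horizontal axis) against log2 fold change in the libraries labelled pericytes (vertical axis) for the 783 genes called in both, interferon-stimulated genes in red. Of these genes 559 lay in the quadrant higher in both and 101 in the quadrant lower in both.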

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

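Tests chosen only after results were seen are the difference between the 2 tables, the range test for lens mRNAs, which replaced the exact test given beside it, both covariate fits, the sum of macrophage genes at low level, and the reading of the pattern-recognition test, first taken as met and then as open. The difference between the vesicle effects in the retina and in the pericyte-labelled libraries was fitted over 13712 genes, of which 1642 differed. The difference was signed, so 1023 had the higher log2 fold change in the retina and 619 the lower, whatever the size of either effect. Of 39 lists 18 differed at the preset correlation and 0 with an estimated correlation, which gave 5 of the 39 an unadjusted p under 0.05, and the estimated-correlation adjusted p of each of the 18 ran from 0.328 to 0.664. Values below are the median over a list of the difference in log2 fold change, retina minus pericyte-labelled, with the adjusted p at the preset correlation. Tissue, time and library set differ between the tables, so none of these differences can be assigned to a cell type.

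Lists with the larger rise in the retina were monocyte and macrophage markers (2.59, adjusted p = 4.7e-12), reactive gliosis (2.07, 2.9e-15), complement and coagulation (1.48, 6.8e-08), Ly6C-low monocyte markers (1.13, 0.025) and extracellular matrix (1.05, 7.0e-07). Smaller differences of that sign were found for alternative activation markers (0.90, 0.0062), angiogenic factors (0.80, 0.00053), the antioxidant response (0.74, 1.4e-05), contractile genes (0.73, 0.0010), antigen presentation (0.44, 0.025), the unfolded protein response (0.25, 0.011), cholesterol biosynthesis (0.23, 0.0099) and ribosomal proteins (0.18, 0.0026). Interferon-stimulated genes rose less in the retina (-1.21, 1.3e-15), with medians of 1.71 there and 2.91 in the other libraries. Lower in the retina relative to the other libraries were rod genes (-0.67, 0.0072), amacrine and horizontal cell markers (-0.58, 0.011), ganglion cell markers (-0.47, 0.0021) and glycolysis genes (-0.34, 0.0072). NF-kB targets (0.0761) and chemokines (0.756) were not called different.

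Lens mRNAs ranged from 0.0120% to 7.19% of counts over the 6 retina libraries. Lens tissue carried over at dissection predicted that other lens fibre genes follow the crystallins, and they did (Pearson's r = 0.999, exact permutation p = 0.0014, adjusted 0.0028 over 2 relations, and Spearman's rho = 1, p = 0.0028, adjusted 0.0028), with r = 0.997 without vesicle libraries 2 and 3. The tables argue against vesicle treatment as the whole cause, since summed lens mRNAs spanned 9.35 log2 units within the vesicle group and 3.49 within PBS, against 1.90 between the group means (exact permutation p = 0.6, smallest possible 0.1). A smaller effect of treatment remains open. Other lens fibre genes would follow the crystallins for any source of lens RNA, so that result does not show when or how the RNA entered.

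Immune genes of the retina were higher with vesicles, and the 123 list members weighed here were chosen by that call. The tables argue against carried-over lens tissue, since with the lens covariate 114 of the 123 stayed called. Their median log2 fold change was 2.56 with it against 2.75 without it. The median absolute deviation of 1.60 is a spread over single members, too wide to judge a shift of the median. The tables also argue against a larger amount of blood, since summed erythrocyte mRNAs changed by -0.0695 ± 0.246 on the log2 scale (exact permutation p = 0.8) while the neutrophil list had a median of 4.86. Erythrocyte mRNAs do not measure leukocytes, so blood with more leukocytes in it stays open. Carried-over contractile tissue stays open, since the contractile sum was itself higher in all 3 vesicle libraries. With it as covariate 44 of 123 stayed called and the median was 2.34 against 2.75 without it, while calls over all genes went from 2449 to 243. In vesicle library 3, with a contractile sum of 260 CPM against 230 CPM in PBS library 3, all 123 members lay above the highest PBS library. They did so in vesicle libraries 1 and 2 too, but the members were chosen by their call. Of the 10 splits of the 6 libraries, 1, the real split, gave as many calls (2449, highest other 0), too few splits for a share under 0.05. A response to the vesicles stays open beside these, untested against a preparation without vesicles. Only the vesicle group carries the i.o. mark in the labels. A difference in how PBS and vesicles were given can therefore not be told apart from that response.

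Immune genes also rose in the pericyte-labelled libraries, where monocyte and macrophage markers had 5 of 19 higher (Cd14, Cybb, Clec4e, Ptprc and Adgre1, list adjusted p = 0.025, and 0.55 with an estimated correlation). Summed mRNA of 12 macrophage genes did not double with treatment and changed by 0.28 ± 0.18 on the log2 scale (101 ± 5.14 to 124 ± 25.6 CPM). The median log2 fold change of the 12 was 0.17, and 2 were called higher. Ptprc, a called gene among them, had log2 fold changes from 1.66 to 2.58 over the alternatives. A sum is carried by its highest genes, which other cells could supply, so it cannot decide whether rare macrophages or microglia doubled. More such cells with treatment, or a response of those in both groups, stays open. The 20 genes under 10 CPM with PBS, out of the 12 and the monocyte and macrophage list, summed to a change of 0.41 ± 0.15, with 4 called higher. A pattern-recognition ligand in the vesicle preparation would raise both NF-kB targets and interferon-stimulated genes, whose medians were 2.55 and 3.01, but the design has no preparation without vesicles, so this and an effect of the vesicles themselves cannot be told apart. Of the 10 splits, 1, the real split, gave as many calls (3365, highest other 0), too few for a share under 0.05.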

How the results depend on the processing

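Alternatives involving lens mRNAs or S6 kinases were added after seeing the data, and the others were fixed before. No called gene changed sign under any alternative in either table. Leaving out 1 library moved the retina count between 1328 and 2909 (higher from 1048 to 2010, lower from 277 to 899), and fewer samples are tested there. In the other libraries it moved the count between 2412 and 3500 (higher from 1382 to 1927, lower from 993 to 1573). An absolute log2 fold change of at least 1 left 1195 genes in the retina (1070 higher, 125 lower) and 629 in the other libraries (503 and 126), which follows from the added threshold. At 10 CPM in 3 libraries 1049 genes were higher in the retina because fewer genes were tested, and at adjusted p under 0.1 the retina had 1369 lower genes and 209 were lower in both settings, by the looser threshold. Without the library with the most lens counts in each group the retina had 1420 calls (1058 higher, 362 lower), of which 1259 were called with all libraries, and fewer samples were tested. Counts stayed within 1.5 times of the reported ones with the lens covariate (2072), without lens genes (2463), with DESeq2 (2984 and 3340), relative log expression (2446 and 3377), no TMM scaling (2323 and 3562) and no low-count filter (2668 and 3416).

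Numbers in the retina column names are not tied to labelled replicates and did not pair the samples (r of 0.18, -0.19 and -0.06). With them as a replicate block 1919 retina genes were called (1395 higher, 524 lower), 1835 of them shared, and 28 lists. The block takes 2 of the 4 residual degrees of freedom, so fewer calls with it do not mean weaker effects. Of the retina genes named in the text, Gfap, Cd44, Aqp4, Ace, Cd36, P2ry13, Trib3, Csrp3, Grn, Cnn2, Nos3, Hk1, Pfkfb4, Vldlr and Slc1a2 lost the call with it (adjusted p from 0.0520 to 0.114). In the pericyte-labelled libraries the replicate numbers did not pair the samples either (r of 0.03, 0.02 and -0.02), and with them as a block 3287 genes were called (1814 higher, 1473 lower), 3178 of them shared, and 15 lists. Of the genes named there, G0s2 alone lost the call with the block (log2 fold change -1.21, adjusted p = 0.0657). In neither table did every library correlate best with its own number.

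Called lists numbered 28 in the retina, between 27 and 31 without 1 library, 25 with fry directional and 36 mixed, and 0 with an estimated correlation. With an estimated correlation camera also refers its statistic to the 4 residual degrees of freedom, and with a preset one to about as many as genes tested. No fit set this apart from gene-to-gene correlation, so the lost calls do not measure such correlation alone. Glycolysis and hypoxia had an estimated correlation of 0.00046, under the preset 0.01, and lost its call too (unadjusted camera p = 0.020 preset and 0.061 estimated). Correlated genes do not account for that loss. In the other libraries 14 were called, between 13 and 15 without 1 library, 23 with fry directional, 33 mixed and 5 with an estimated correlation. The ribosomal list without S6 kinases left both counts at 28 and 14. Directions of 2 uncalled genes reversed in the pericyte-labelled libraries, Slc1a3 (between -0.0181 and 0.0165 without 1 library) and Acta2 (-0.0119 without TMM scaling). Dropping TMM scaling moved log2 fold changes in these libraries by a median of -0.0478, a shift that takes Acta2 below 0. For Slc1a3 the cause was not tested. Among genes followed through the alternatives, not all of them named in the text, fits without 1 library ended the call with the same direction 136 times in the retina and 74 times in the other libraries, and made a call 4 times and 1 time. Fits without the library with the most lens counts in each group ended 42 calls with the same direction, and the lens covariate ended 11. Simulated 1.5-fold changes were recovered at 19.7% in the retina, so small changes there are easily missed.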

Other observations

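The astroglial test in this part was chosen after the levels were seen, and the other values come from lists fixed before the data were examined. In the retina, angiogenic and vascular factors had 8 of 22 higher and Nos3 lower (11 and 1 adjusted over the list alone, median 0.51, camera adjusted p = 8.1e-06, adjusted p = 0.16 with an estimated correlation). Ribosomal proteins had 20 of 89 higher and 3 lower (Rpl23a, Rpl28 and Rps15) (33 and 3 adjusted over the list alone, median 0.24, camera adjusted p = 0.0046, adjusted p = 0.50 with an estimated correlation). Rps27l went from 49.6 ± 4.28 to 100.1 ± 12.8 CPM. Glycolysis and hypoxia genes had 4 of 25 higher (Pfkfb3, Egln3, Hk1 and Pfkfb4) and 11 lower (4 and 12 adjusted over the list alone, median -0.30, camera adjusted p = 0.030, adjusted p = 0.18 with an estimated correlation), a call lost without PBS library 3 (adjusted p = 0.0540) or vesicle library 1 (0.0938). Pfkfb3, a regulator of glycolysis, rose from 13.5 ± 0.458 to 28.7 ± 4.49 CPM, and the glycolytic enzyme Aldoa fell from 4206 ± 311 to 2723 ± 281 CPM. In the unfolded protein and integrated stress response 11 of 28 rose and 3 fell (Ddit4, Vldlr and Trib3) (12 and 4 adjusted over the list alone, median 0.36, camera adjusted p = 0.0051, adjusted p = 0.43 with an estimated correlation). Manf went from 98.6 ± 7.21 to 157 ± 13 CPM. Cholesterol biosynthesis had 7 of 25 higher and 0 lower (8 and 0 adjusted over the list alone, camera adjusted p = 0.25). Msmo1 went from 219.5 ± 4.97 to 351 ± 31.9 CPM.

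Other retina lists were not called by camera. Heat shock proteins had 4 of 16 higher and 2 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.23), and cell cycle genes 2 of 34 higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.89). Oxidative phosphorylation had 1 of 36 higher and 2 lower (0 and 2 adjusted over the list alone, camera adjusted p = 0.85). Markers of vessels and their neighbours were mixed. Pericyte markers had 3 of 18 higher and 2 lower (4 and 4 adjusted over the list alone, camera adjusted p = 0.79), endothelial markers 1 of 16 higher and 1 lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.94), and fibroblast markers 2 of 17 higher and 0 lower (2 and 0 adjusted over the list alone, camera adjusted p = 0.085). Genes of cornea, iris and ciliary body had 2 of 17 higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.94). Astrocyte, oligodendrocyte and Schwann cell markers had Slc1a2 of 11 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.49), and erythrocyte and platelet genes 2 of 10 higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.64). Among the retina genes named here, Nos3, Rpl28, Rps15, Egln3, Hk1, Pfkfb4, Vldlr, Trib3 and Slc1a2 lost the call without PBS library 2 and, but for Egln3, without at least 2 others (adjusted p from 0.0525 to 0.184). Of 2 tested lymphocyte markers, Gzma, a granzyme, rose (log2 fold change 4.53 ± 0.76, adjusted p = 0.0041, and 0.0587 without the library richest in lens mRNAs in each group).

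In the pericyte-labelled libraries, extracellular matrix genes had 12 of 37 higher and 0 lower (13 and 0 adjusted over the list alone, camera adjusted p = 0.065). Timp1 went from 52.4 ± 4.80 to 115 ± 11.4 CPM. Angiogenic and vascular factors had 10 of 25 higher and 6 lower (10 and 6 adjusted over the list alone, camera adjusted p = 0.28). Angptl4 went from 8.06 ± 1.36 to 36.2 ± 7.01 CPM and Apln, a vascular peptide, fell from 67.8 ± 1.40 to 35.9 ± 1.22 CPM. Of cholesterol biosynthesis genes 0 of 25 rose and 6 fell (0 and 6 adjusted over the list alone, camera adjusted p = 0.065). Sqle went from 157 ± 6.71 to 121 ± 3.81 CPM. Glycolysis and hypoxia genes had 3 of 26 higher and 3 lower (4 and 3 adjusted over the list alone, camera adjusted p = 0.99), the unfolded protein response 6 of 28 and 5 (7 and 6 adjusted over the list alone, camera adjusted p = 0.95), and the antioxidant response 3 of 21 and 3 (3 and 4 adjusted over the list alone, camera adjusted p = 0.59). Slc7a11, a cystine transporter, went from 19.0 ± 3.87 to 52.6 ± 3.53 CPM. Among heat shock proteins Hspb1 of 16 rose (1 and 0 adjusted over the list alone, camera adjusted p = 0.99). For oxidative phosphorylation edgeR and DESeq2 called 0 of 36 genes, with 1 at unadjusted p under 0.05 (0 and 0 adjusted over the list alone, camera adjusted p = 0.97). Of 13 mitochondrially encoded mRNAs mt-Co3 was called higher (0 and 0 adjusted over the list alone, camera adjusted p = 0.97). It was at 21.9 ± 1.11 CPM with PBS and 27.2 ± 4.94 CPM with vesicles, against 9382 ± 487 and 9641 ± 1052 CPM for mt-Co1. Why so few reads were counted for mt-Co3 was not tested. The ribosomal name pattern had 2 called genes of 95, the S6 kinases Rps6ka4 (higher) and Rps6ka5 (lower) (1 and 0 adjusted over the list alone, camera adjusted p = 0.61).

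Alternative activation markers in these libraries had 5 of 12 higher and 0 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.18). Arg1 rose from 0.202 ± 0.0440 to 1.78 ± 0.435 CPM. Ly6C-low monocyte markers had Cebpb of 11 higher (1 and 0 adjusted over the list alone, camera adjusted p = 0.99) and homeostatic microglia markers Olfml3 of 9 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.41). Endothelial markers had Flt1 of 12 higher and 3 lower (Kdr, Slco1a4 and Slco1c1) (2 and 3 adjusted over the list alone, camera adjusted p = 0.99), and fibroblast markers Ly6a of 14 higher and Pdgfra lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.73). Neuronal lists of the retina had few tested genes here, and their results were 2 higher and 1 lower of 10 for ganglion cells (3 and 1 adjusted over the list alone, camera adjusted p = 0.62), 1 and 1 of 8 for amacrine and horizontal cells (2 and 1 adjusted over the list alone, camera adjusted p = 0.99) and 0 and 3 of 6 for bipolar cells (0 and 4 adjusted over the list alone, camera adjusted p = 0.14). Cones had Thrb lower of 5 (0 and 1 adjusted over the list alone, camera adjusted p = 0.73). Of 5 rod genes edgeR called 0, with 0 higher and 0 lower at unadjusted p under 0.05 and 0 higher and 0 lower by DESeq2 (0 and 0 adjusted over the list alone, camera adjusted p = 0.97). Of 9 lens genes edgeR called 0, with 0 higher and 2 lower at unadjusted p under 0.05 and 0 higher and 0 lower by DESeq2 (0 and 0 adjusted over the list alone, camera adjusted p = 0.34). Pigment epithelium genes had Enpp2 higher and Rdh5 lower of 6 (1 and 1 adjusted over the list alone, camera adjusted p = 0.99), and cornea, iris and ciliary body genes 3 higher and 1 lower of 11 (3 and 1 adjusted over the list alone, camera adjusted p = 0.34). Among the genes named here, Hspb1, mt-Co3, Rps6ka5, Olfml3, Slco1a4, Slco1c1 and Thrb lost the call without PBS library 2 and, but for Hspb1, without at least 2 others (adjusted p from 0.0515 to 0.264). The 2 tested lymphocyte markers and 3 tested erythrocyte and platelet genes gave 0 calls by edgeR, with 0 higher and 0 lower and 1 higher and 0 lower at unadjusted p under 0.05 and 0 higher and 0 lower and 0 higher and 0 lower by DESeq2.

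The libraries labelled pericytes held high levels of mRNAs usually found in astroglia. Of the 21 genes of the Müller glia list, 16 (76.2%) were at 10 CPM or more in all 6 libraries, against 7 of 22 (31.8%) of the pericyte list. Of the 21 genes, 2 stand in other lists and 0 in the pericyte list, and the list of astrocyte, oligodendrocyte and Schwann cell markers had 38.9% at that level, contractile genes 65% and fibroblast and meningeal markers 50%. With PBS, Sox2 was at 432 ± 8.43 CPM, Slc1a3 at 434 ± 10.6 CPM, Hepacam at 324 ± 2.79 CPM, Aldh1l1 at 219 ± 7.01 CPM and Slc1a2 at 56.0 ± 2.05 CPM, all chosen after their values were seen. Some pericyte markers, also chosen then, had few or no counts, given here over the PBS and then the vesicle libraries. Higd1b had 0 and 0, Des 0 and 1, Abcc9 0 and 6, and Kcnj8 8 and 8. Other pericyte markers were higher, with Pdgfrb at 59.7 ± 3.48 CPM and Cspg4 at 11.9 ± 0.900 CPM with PBS. Astroglial cells in the cultures, beside cells of other kinds, are a candidate explanation, and a different culture under this label is another, which these counts cannot part from the first. No sort or gate is stated in the labels.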
